A study of Mus musculus with 3 samples.

How the data were processed

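Gene expression in the developing mouse kidney was re-analysed from the deposited value table of 3 arrays. Metanephroi (the first stage of the permanent kidney) from CD1 mouse embryos at 11.5 days post coitum (dpc) and fetal kidneys at 13.5 dpc were microdissected as pools of both sexes, per the labels. Amplified RNA was labelled through amino allyl groups, and both ages were hybridised together on each of 3 two-channel Compugen mouse oligonucleotide arrays. Channel 1 held the 11.5 dpc material and channel 2 the 13.5 dpc material. Per the labels, arrays 1 and 2 had the dye order red/green and array 3 the order green/red.

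The deposited values are log2 ratios, and their base was found from the values. Raising 2 to each value between -3 and 2 gave a whole multiple of 0.001 for 100% of them, within 0.02 of that step. The same test gave 4.42% for e and 4.26% for 10. Images were quantified with ImaGene 5.5, per the labels. The labels carry 2 accounts of the normalisation. One names print-tip loess followed by a normalisation between arrays in R. The other describes a Lowess curve through 20% of the data at each point, used to adjust the control channel, with values of that channel under 10 set to 10. Which of them made the deposited log2 ratios is not given in the sources used here. Spot intensities were not used here, so background, saturation and dim spots could not be assessed, and no filter on signal was applied.

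The table held 22702 features, of which 883 control or blank features were left out. Of the 21819 gene features, 16656 had 1 gene symbol in the platform annotation, 137 had several and 5026 had none; features with several symbols were left unnamed. Symbols were updated through Entrez identifiers against the GRCm38.p6 gene table, which matched 15970 features and renamed none. No genome coordinates were used. The 20386 gene features with a value on all 3 arrays were kept, and features of 1 symbol were averaged, which gave 19015 rows (14433 named, 4582 unnamed). Among 971 genes with several features, the feature means had opposite signs in 514 and lay over 1 log2 unit apart in 132.

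The direction of the ratio is likely 11.5 over 13.5 dpc, because the labels pair that order of ages with red/green and put 11.5 dpc in channel 1; it is not settled. Array 3 was to be turned only if its Pearson correlation with both other arrays was below 0. It was 0.11 with array 1 and -0.12 with array 2 (-0.0031 by Spearman), across genes, which are not independent replicates, so array 3 was used as deposited. A list of genes expected to be higher at 13.5 dpc was fixed as a check of the labels.

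Mean log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Nothing in the labels says that the arrays came from separate RNA extracts, so limma's p-values measure only the spread between these arrays, which may be technical, and their number limits the precision. A fit with an added dye term left 1 residual degree of freedom. Rows with a ratio of at least 2-fold and 1 sign on every array were counted as a description without a test. Gene lists for 28 cell types, structures and pathways, and the label check, were tested with camera at a preset correlation of 0.01 between genes, adjusted over 29 lists; an estimated correlation and ranks were alternatives, as was fry, which tests a list against 0 and not against the other genes. The ribosomal list was taken by symbol prefix and so also holds Rps6k kinases and Rpl3l, and the solute carrier list also holds Slc9a3r2. Of the genes in the 28 lists, 77 stand in more than 1, the label check not counted. The lists, tests and naming rule were fixed before the data were examined.

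Named genes were the 12 highest and 12 lowest past the threshold with 1 sign on all arrays, filled up by the largest limma statistics where too few passed (since none passed, all 24 came by that statistic), up to 4 members of each list past the threshold or otherwise the 2 with the smallest p, and 26 genes of kidney and blood development named in any case. The last set included Ren1, Csf1r and Hbb-b1, which had no row with a value on all arrays. Other members named below were past the threshold adjusted over the list alone or at least 2-fold on every array, and were chosen after their values were seen, as were Twist1, Meis1, Cdh5 and further members named with their list.

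The procedure was tested on simulated data with 19015 rows and 200 changed rows. With the values of each array shuffled separately, limma called 0, 16, 74 and 92% of rows changed by 1, 2, 3 and 4 log2 units, and no unchanged row. The 2-fold count took 14, 86, 94 and 100% of them and 6 unchanged rows. With noise drawn from each row's residuals, which spreads an extreme value on 1 array over all 3, limma called 0, 20, 38 and 60%, and 134 unchanged rows were at least 2-fold. The residual noise was run first, and shuffled arrays were added after its output had been seen. Camera called 50 of 50 lists of 30 genes shifted by 0.5 and 1 of 50 unchanged lists. These lists came from the shuffled arrays, where shuffling removes any correlation between genes and any trend along the library. The 1 false call therefore does not cover lists of correlated genes, such as the ribosomal list with an estimated correlation of 0.25. Alternatives were a dye term, median centring, scale and quantile normalisation, a robust variance prior, an ordinary one-sample test, a floor on the ratios, rows with a value on 2 arrays, features tested singly, other thresholds, array 3 turned, and each array left out. Array weights, a running median along the oligonucleotide library, and other correlations between arrays were added after the data were seen. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.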

Results

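Both ages were compared on 3 arrays, each carrying metanephroi of 11.5 dpc and fetal kidney of 13.5 dpc from CD1 mice. At 11.5 dpc the ureteric bud has just entered the metanephric mesenchyme, and by 13.5 dpc the bud has branched and the first nephrons are forming. The comparison asks which genes differ in level between these ages. Values were obtained for 20601, 21274 and 21563 gene features on arrays 1, 2 and 3. The log2 ratios had medians of 0.010, 0.065 and -0.091 and standard deviations of 0.56, 0.79 and 0.97. Positive values are read as higher at 11.5 dpc, the likely direction; every direction below turns if that reading is wrong.

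Genes of the renal vesicle and of the comma- and S-shaped bodies, the first epithelial stages of the nephron, lay lower at 11.5 than at 13.5 dpc. They included the Notch ligand Dll1, 4.74-fold lower with a mean log2 ratio of -2.25 ± 0.55 (SD, n = 3 arrays), and the Notch targets Heyl (-1.88 ± 0.24) and Hes5 (-1.35 ± 0.27). Genes of the extracellular matrix and endothelium also lay lower at 11.5 dpc, among them Col6a1 (-1.34 ± 0.07) and Cdh5 (-0.55 ± 0.11). Genes of red blood cells lay higher at 11.5 dpc: the embryonic globin Hbb-bh1 had a mean log2 ratio of 4.07 ± 1.09 and the erythroid transcription factor Klf1 one of 2.18 ± 0.22. These 4 lists passed camera at its preset correlation (adjusted p from 2.52e-09 to 7.78e-05) and not with an estimated one (adjusted p = 0.184 for each), and no single gene passed limma's adjusted threshold. Their estimated correlations were -0.029 (renal vesicle), 0.0062 (matrix), -0.0032 (endothelium) and 0.011 (erythroid), near or below the preset 0.01. For these lists the loss thus goes with the 2 residual degrees of freedom of the estimated form, not with a high estimated correlation. The estimates rest on the same 2 degrees of freedom, so they cannot exclude correlated genes.

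Of 19015 rows tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.197. At an unadjusted p under 0.05 there were 1757 rows, 793 higher and 964 lower at 11.5 dpc, against 950.75 expected with no change. There were 736 such rows without array 1, fewer than expected, and 1020 without array 2. Without array 3 there were 2346, more of them higher (1343) than lower (1003). Arrays 1 and 2 have the same dye order, so in that last refit age and dye cannot be told apart. The ordinary one-sample test also passed 0 rows, with 1829 at an unadjusted p under 0.05. In the limma fit with a dye term, 0 rows passed for dye (2409 at an unadjusted p under 0.05) and 0 for age (2669, with 1396 higher and 1273 lower). The same sign on all 3 arrays was found for 35.3% of rows, against 25% by chance if the arrays were independent. Arrays 1 and 2 share a dye order and correlated at 0.27, so the excess need not all come from age. The share of 35.3% is for array 3 as deposited, an orientation that is not settled. A difference of at least 2-fold with 1 sign on every array was found for 130 rows, 47 higher and 83 lower at 11.5 dpc. With the sign of 1 array turned, this count was 42 for array 3, 17 for array 2 and 7 for array 1. Simulated data gave 6 such unchanged rows with shuffled arrays and 134 with noise from the rows' residuals. Shuffling removes whatever the arrays share, and the residual noise spreads an extreme value on 1 array over all 3. Neither count is therefore a chance level for the 130 rows.

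**Figure D1:**
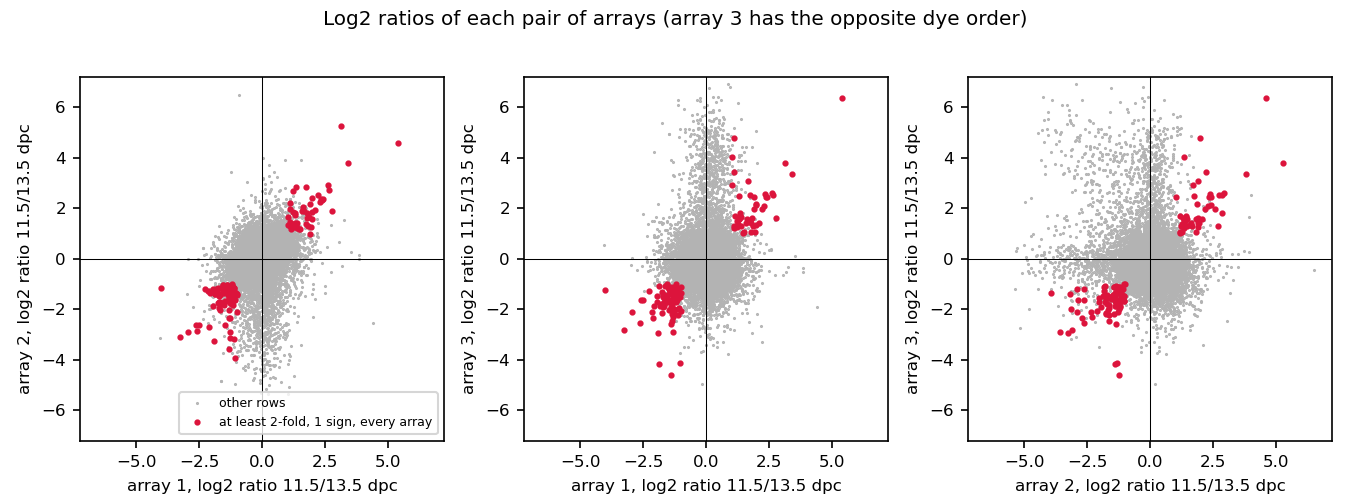
Log2 ratios of 11.5 over 13.5 dpc on each pair of arrays, with 1 point per row (19015 rows, grey) and the 130 rows of at least 2-fold and 1 sign on every array in red. Pearson correlations across features were 0.27 between arrays 1 and 2, 0.11 between 1 and 3, and -0.12 between 2 and 3, the last being -0.0031 by Spearman and 0.0012 without features beyond 2 on array 2 or 3.

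Of the 12 genes higher at 11.5 dpc with the largest limma statistic and 1 sign on all arrays, array 3 as deposited, the glucose transporter gene Slc2a1 had the highest ratio, with a mean log2 ratio of 5.44 ± 0.89 (43.4-fold, SD over 3 arrays). The erythroid membrane protein gene Ermap followed at 3.51 ± 0.25, and the carbonic anhydrase gene Car2 at 2.70 ± 0.18. Gfra3, a receptor of the GDNF family, had 2.63 ± 0.11. The transporter genes Slc22a16 and Slc20a2 had 2.41 ± 0.02 and 2.23 ± 0.10, and the prostaglandin receptor gene Ptger3 had 2.25 ± 0.28. Klra2, Art5, the leptin receptor gene Lepr and Rec114 had 2.42, 2.39, 1.99 and 1.61. Among the 12 lower genes picked the same way, the opioid precursor gene Penk had -3.06 ± 0.23, the peptidase gene Dpp4 had -2.65 ± 0.48 and the potassium channel gene Kcnj8 had -2.59 ± 0.04. Pcp4 had -2.39 ± 0.29, the guanylate cyclase subunit gene Gucy1b1 had -1.84 ± 0.13 and the transcription factor gene Klf4 had -1.73 ± 0.07. Cdh16, a cadherin of kidney epithelium, had -1.62 ± 0.12, and Col4a3, a collagen of the glomerular basement membrane, had -1.57 ± 0.11. Rab6a, Tomm6 and Cdc42ep2 had -1.76, -1.65 and -1.62. The limma adjusted p of these 24 genes lay between 0.197 and 0.326. Their choice and their order by mean hold for array 3 as deposited, an orientation that is not settled.

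**Figure D2:**
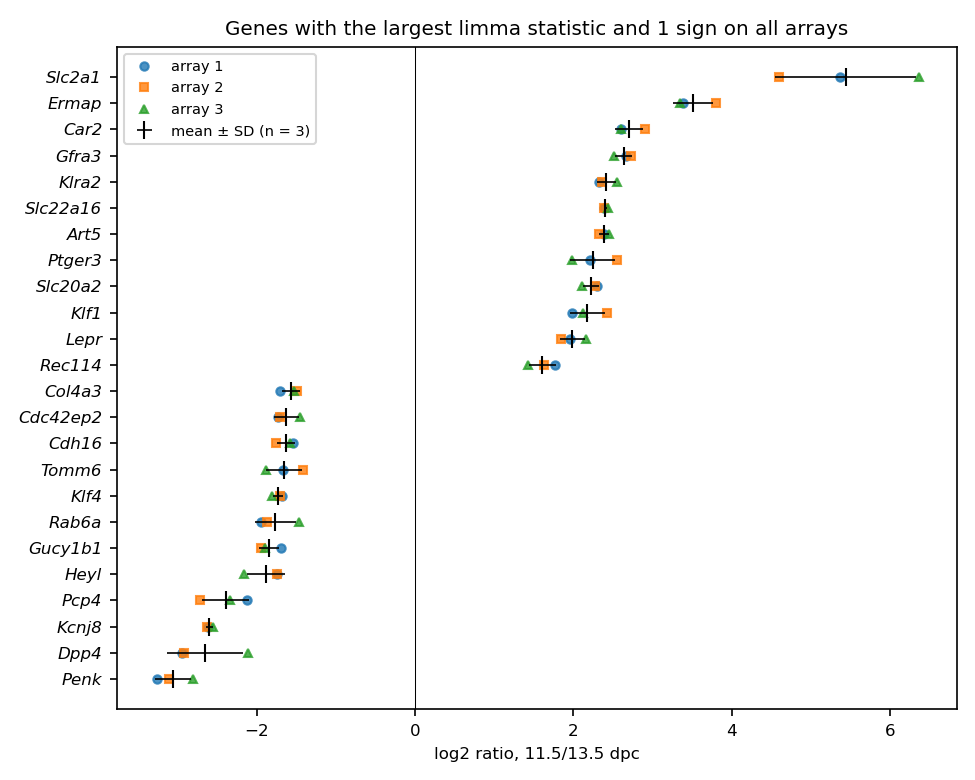
Log2 ratios of 11.5 over 13.5 dpc on the 3 arrays for the 12 higher and 12 lower genes with the largest limma statistic and 1 sign on all arrays, with 1 marker per array and the mean with its SD as a black tick and line. Among these 24, with array 3 as deposited, Slc2a1 had the highest mean (5.44) and Penk the lowest (-3.06), and no gene passed limma's adjusted threshold.

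Of the 29 measured members of the renal vesicle, comma- and S-shaped body list, 20 were negative on all 3 arrays and the median log2 ratio was -0.50 (camera adjusted p = 2.52e-09; adjusted p = 0.184 with an estimated correlation). Of these members 13 were lower at 11.5 dpc adjusted over the list alone, and 0 over all genes tested. The transcription factor gene Sim2 had -2.71 ± 0.72, Npy had -1.27 ± 0.16, Hey1 had -0.97 ± 0.23, and Wnt4, the signal that starts nephron epithelium, had -1.02 ± 0.34. The Notch list gave a median of -0.29 over 25 members (camera adjusted p = 3.19e-06; adjusted p = 0.184 with an estimated correlation). Of the Notch genes 6 were lower adjusted over the list alone and 0 over all genes tested; they were Heyl, Dll1, Hes5, Hey1, the endothelial ligand Dll4 (-0.86 ± 0.10) and Dlk1 (-1.55 ± 0.19). Several of these stand in both lists.

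Among 44 genes of the ureteric bud and collecting duct, the median was -0.27 and 17 were negative on all arrays (camera adjusted p = 2.75e-05; adjusted p = 0.184 with an estimated correlation). Cdh16 and the sodium channel subunit genes Scnn1b (-1.35 ± 0.18) and Scnn1g (-1.17 ± 0.22) made up the 3 lower adjusted over the list alone, against 0 over all genes tested. The bud tip receptor gene Ret had 0.30 ± 0.20, which became -0.050 with array 3 turned. Wnt11 had -0.092 ± 0.12, which became 0.031 after a running median along the library was subtracted. Nephron progenitor genes had a median of -0.30 over 28 members (camera adjusted p = 0.0218; adjusted p = 0.321 with an estimated correlation), with 0 past either adjustment; the list was not past camera without array 2 (adjusted p = 0.142) or array 3 (0.0621). Cited1 had -0.85 ± 0.37, Pax2 -0.64 ± 0.55, Wt1 -0.31 ± 0.20, Gdnf -0.29 ± 0.16 and Rspo3 0.66 ± 0.31. With array 3 turned, Pax2 (0.086) and Gdnf (0.026) were positive. Six2 had -0.17 ± 0.44 and was positive without array 1 (0.064). Podocyte genes had a median of -0.23 over 26 members (camera adjusted p = 0.0206; adjusted p = 0.57 with an estimated correlation), and Col4a3 was the 1 lower adjusted over the list alone, with 0 over all genes tested. Without array 3 the podocyte median was -0.074 (adjusted p = 0.207), and the list was also not past camera without array 2 (0.0596) or with array weights (0.0709). Nes had -0.87 ± 0.25, Nphs1 -0.22 ± 0.47 and Podxl -0.032 ± 0.37; Nphs1 was positive without array 3 (0.045), and Podxl without array 2 (0.17) and after the running median (0.0015).

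Matrix genes had a median of -0.35 over 50 members, of which 28 were negative on all arrays (camera adjusted p = 2.65e-08; adjusted p = 0.184 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher at 11.5 dpc, and 0 over all genes tested. The lower ones included the laminin gene Lama4 (-1.43 ± 0.12), Bgn (-1.25 ± 0.07), Sparc (-1.29 ± 0.24) and Tnc (-1.43 ± 0.40), and the higher one was the cartilage collagen gene Col9a1 (1.56 ± 0.42). Tnc and Ogn are each the average of 2 features over 1 log2 unit apart, with feature means of -2.01 and -0.85 for Tnc and of -2.55 and -0.55 for Ogn. Ogn had -1.55 ± 0.81, Col1a1 -0.48 ± 0.19 and Col3a1 0.063 ± 0.12, the last being -0.0035 without array 3. Endothelial genes had a median of -0.32 over 36 members, 18 of them negative on all arrays (camera adjusted p = 7.78e-05; adjusted p = 0.184 with an estimated correlation). None passed adjusted over the list alone or over all genes tested (0 and 0, with 8 lower at an unadjusted limma p under 0.05). Icam2 had -0.83 ± 0.10 and Pecam1 -0.67 ± 0.50.

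The erythroid list had a median of 0.39 over 27 members, 15 of them positive on all arrays (camera adjusted p = 1.75e-06; adjusted p = 0.184 with an estimated correlation). Of these, 8 were higher at 11.5 dpc adjusted over the list alone and 0 over all genes tested: Ermap, Car2, Klf1, Hbb-bh1, the blood group gene Rhd (1.64 ± 0.25), the haem synthesis gene Alas2 (1.28 ± 0.31), Blvrb (1.23 ± 0.20) and Hemgn (1.01 ± 0.28). The embryonic globins Hbb-y and Hba-x had 1.17 ± 1.02 and 0.47 ± 0.20, and Hba-a1 had 0.33 ± 0.16. Hbb-y had 0.19, 2.23 and 1.10 on arrays 1, 2 and 3. Ribosomal protein genes had a median of 0.19 over 76 members, 45 of them positive on all arrays (camera adjusted p = 3.83e-06; adjusted p = 0.57 with an estimated correlation), with 0 past either adjustment. The smallest p in that list belonged to Rpl7l1, a ribosomal protein-like gene, and Rps19bp1, which encodes a protein that binds a ribosomal protein, with 0.45 ± 0.10 and 0.41 ± 0.13. Oxidative phosphorylation genes had a median of 0.16 over 80 members (camera adjusted p = 0.0204; adjusted p = 0.57 with an estimated correlation), with 0 past either adjustment, while Cox6b1 and Uqcrc2 had -0.63 ± 0.29 and -0.54 ± 0.21. Without array 1 that median was 0.11 (adjusted p = 0.288), and without array 3 the adjusted p was 0.0585.

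Neuron, glia and neural crest genes had a median of -0.24 over 28 members (camera adjusted p = 0.0132; adjusted p = 0.321 with an estimated correlation). Uchl1 (-1.10 ± 0.24) and Hand2 (-1.09 ± 0.25) were the 2 lower adjusted over the list alone, with 0 over all genes tested. Gonad, adrenal, germ cell and mesothelium genes had a median of -0.22 over 25 members (camera adjusted p = 0.0142; adjusted p = 0.326 with an estimated correlation). None passed either adjustment (0 and 0, with 4 lower at an unadjusted limma p under 0.05); the steroid enzyme gene Cyp11a1 had -0.88 ± 0.30 and the mesothelial gene Msln -1.02 ± 0.45. Wnt genes had a median of -0.17 over 36 members (camera adjusted p = 0.0206; adjusted p = 0.321 with an estimated correlation), and FGF and RET genes -0.19 over 25 (camera adjusted p = 0.0271; adjusted p = 0.321 with an estimated correlation). Without array 1 the Wnt median was -0.092 (adjusted p = 0.0853) and that of FGF and RET -0.15 (0.101); Wnt was also not past camera without array 3 (0.0585), nor FGF and RET without array 2 (0.336) or with a dye term (0.102). Dkk1 had -1.03 ± 0.30, Etv4 -0.78 ± 0.51 and Hs2st1 -0.45 ± 0.19. Cell cycle genes had a median of -0.12 over 66 members (camera adjusted p = 0.0281; adjusted p = 0.47 with an estimated correlation), while Kif2c and Rfc3 had 0.75 ± 0.07 and 0.66 ± 0.09. In these last 3 lists 0 members passed adjusted over the list alone and 0 over all genes tested. The cell cycle list was not past camera without array 2 (adjusted p = 0.266), without array 3 (0.0695) or with a dye term (0.0565), neuron without array 1 (0.0861), or gonad without array 3 (0.0719). The gonad median was -0.14 and -0.13 without arrays 1 and 2. Mki67 had -1.38 ± 2.16, with -3.87 on array 2 and -0.10 and -0.15 on arrays 1 and 3.

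**Figure D3:**
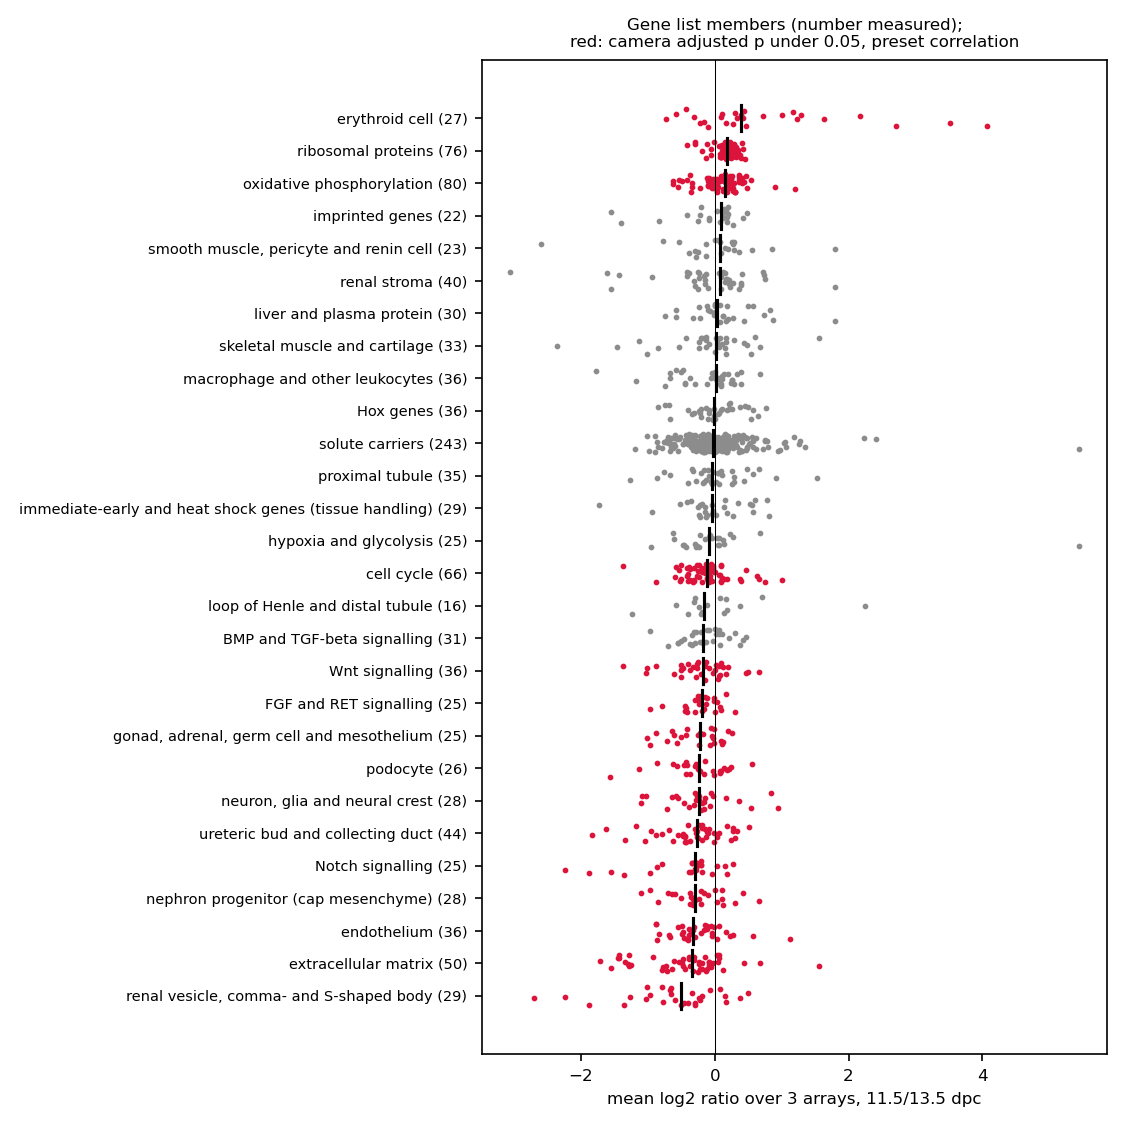
Mean log2 ratio of 11.5 over 13.5 dpc over 3 arrays for each measured member of 28 gene lists (1 point per gene, black bars at list medians, points in red where camera's adjusted p was under 0.05 at the preset correlation). Medians ran from -0.50 for the renal vesicle, comma- and S-shaped body list to 0.39 for the erythroid list; no list passed with an estimated correlation, where the smallest adjusted p was 0.184.

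Genes of the later nephron did not pass as lists. The proximal tubule list had a median of -0.036 over 35 members (camera adjusted p = 0.976), with Anpep at -1.27 ± 0.59, Dpep1 at 0.66 ± 0.36 and Lrp2 at -0.34 ± 0.60. The loop of Henle and distal tubule list had a median of -0.15 and a mean of 0.019 over 16 members (camera adjusted p = 0.722). Adjusted over the list alone, Ptger3 was the 1 higher and Sim1 (-1.24 ± 0.44) the 1 lower, and 0 passed over all genes tested. Without 1 array the loop of Henle median ran from -0.29 (array 2) to -0.026 (array 1), and the proximal tubule median was -0.050, 0.021 and 0.028 without arrays 1, 2 and 3. Umod had -0.11 ± 0.16 and the water channel gene Aqp2 -0.44 ± 0.52. The list of genes expected to be higher at 13.5 dpc had a median of -0.29 over 25 members (camera adjusted p = 0.00645; adjusted p = 0.321 with an estimated correlation), which goes the way the labels read. It was -0.18 without array 3 (adjusted p = 0.0374) and 0.064 with array 3 turned (adjusted p = 0.886). Of its members 1 was lower adjusted over the list alone, Cdh16, and 0 over all genes tested. By mean, 21 members were lower and 4 higher at 11.5 dpc, the globin gene Hba-a1 (0.33) among the higher. The check shares members with the matrix, podocyte and ureteric bud lists, so it is not separate evidence for their direction.

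At the preset correlation 16 of the 29 lists passed camera, 3 higher and 13 lower at 11.5 dpc with the label check among the lower, and 0 passed with an estimated correlation (6 at an unadjusted p under 0.05), while fry, which asks whether a list differs from 0 and not from the other genes, passed 7. The 16 became 0 with array 3 turned, 10 without array 3 and 8 after the running median along the library, while the renal vesicle, matrix, Notch, ureteric bud, endothelial, erythroid, ribosomal and label check lists passed in each of the 12 refits other than array 3 turned. Each of those refits kept the preset correlation of 0.01, while the estimated one was 0.25 for the ribosomal list. The ribosomal and label check lists did not pass fry (adjusted p = 0.151 and 0.105), and the others named here did. The running median ended the calls of nephron progenitor (median -0.19, adjusted p = 0.152), podocyte (-0.12, 0.156), neuron (-0.18, 0.0542), gonad (-0.15, 0.0601), cell cycle (-0.12, 0.218), Wnt (-0.083, 0.439), FGF and RET (-0.11, 0.423) and oxidative phosphorylation genes (0.14, 0.0601).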

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

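The array weights, the running median along the oligonucleotide library and the other correlations between arrays were chosen after the data were seen. Limma passed 0 rows under each alternative, with 736 to 2669 at an unadjusted p under 0.05, and the dye term passed 0 rows with and without median centring (2409 at an unadjusted p under 0.05 without it). The count of rows at least 2-fold on every array was 130, stayed between 130 and 146 under median, scale and quantile normalisation, the floor, single features and the running median, and was 42 with array 3 turned. It was 479 at 1.5-fold, 28 at 3-fold, and 266 to 341 without 1 array, where fewer arrays had to meet the rule. Of the 130 rows, 125 were shared with the count after median centring and 115 with that after the running median. The 16 lists past camera became 0 with array 3 turned, 0 with an estimated correlation, 7 with fry (a test against 0), 8 after the running median, and 10 to 12 without 1 array. Other refits passed 14 to 16. The label check had a median of -0.29, which was 0.064 with array 3 turned and, by construction, 0.29 with every sign turned. With array 3 turned, podocyte went from -0.23 to 0.095 and cell cycle from -0.12 to 0.030. For these changes the cause was not tested. The correlation of arrays 1 and 3 was 0.11, 0.13 by Spearman and 0.096 without features beyond 2 on array 2 or 3; that of arrays 2 and 3 was -0.12, -0.0031 and 0.0012. Of 86 named genes, 24 of them picked for 1 sign on all arrays, 8 changed sign with array 3 turned, 1, 1 and 3 without array 1, 2 and 3, 1 with array weights and 2 after the running median. The 8 were Etv4, Ogn, Gdnf, Ret, Pax2, Nphs1, Acta2 and Col3a1. Only Six2, Wnt11, Nphs1, Podxl, Lrp2, Aqp2, Acta2 and Col3a1 lacked 1 sign on all arrays. For every other named gene, leaving out or weighting an array could not change the sign. A variance prior with a trend and a filter on dim features were not run, since both need signal intensities, and signal over background limits every ratio to an unknown extent; a floor of 0.01 moves no value.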

Other observations

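The tests of sign patterns, extreme values and erythroid genes weighed here were chosen after their results had been seen, and the bounds they were held to were worded then; the running median along the library was chosen after the trend was seen but before its result. Stromal genes lay on both sides of 0 within 1 list. Of 40 measured stromal genes, 4 were lower at 11.5 dpc adjusted over the list alone (Penk, Dlk1, Tnc, whose 2 features differ by 1.16, and Smoc2, the last at -1.61 ± 0.23, SD over 3 arrays), and 0 over all genes tested by limma. The stromal progenitor gene Foxd1 had 0.72 ± 0.36, Meis1 0.73 ± 0.14 and Twist1 0.75 ± 0.13, each positive on all arrays and none past either adjustment. The list's median was 0.072 and its mean -0.11 (camera adjusted p = 0.661). In the smooth muscle, pericyte and renin cell list (23 members, median 0.085, mean -0.0061, adjusted p = 0.791), Kcnj8 was the 1 lower adjusted over the list alone; Tpm1 had 0.85 ± 0.21. Acta2 had -0.26 ± 1.20, with -1.62 on array 3, and was positive without it (0.42) and with array weights (0.069). In the skeletal muscle and cartilage list (33 members, median 0.024, mean -0.11, adjusted p = 0.944), Acta1 (-2.36 ± 0.65) and Myl1 (-1.46 ± 0.47) were the 2 lower and Col9a1 the 1 higher adjusted over the list alone. Of 22 imprinted genes (median 0.10, mean -0.11, adjusted p = 0.944), Dlk1 and H19 (-1.41 ± 0.36) were the 2 lower adjusted over the list alone. In each of these lists 0 passed over all genes tested.

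Solute carriers had a median of -0.031 and a mean of 0.021 over 243 members (camera adjusted p = 0.994), with Slc2a1, Slc20a2 and Slc22a16 the 3 higher adjusted over the list alone. Slc2a1 was also the 1 higher in the hypoxia and glycolysis list (25 members, median -0.080, mean 0.076, adjusted p = 0.661), where Bnip3 had 0.68 ± 0.26. Klf4 was the 1 lower among 29 immediate-early and heat shock genes (median -0.040, adjusted p = 0.722), with Gadd45g at 0.56 ± 0.21. Leukocyte genes had a median of 0.021 and a mean of -0.13 over 36 members (adjusted p = 0.944), with the neutrophil genes S100a8 and S100a9 at -0.68 ± 0.10 and -0.58 ± 0.16. Liver and plasma protein genes had 0.040 over 30 members (adjusted p = 0.544), with Apoe at 0.87 ± 0.11 and Alb at -0.57 ± 0.33. BMP and TGF-beta genes had -0.17 over 31 (adjusted p = 0.232), with Tgfb1 at -0.71 ± 0.33 and Ltbp3 at -0.55 ± 0.15. Hox genes had -0.016 over 36 (adjusted p = 0.722), with Hoxb6 at -0.67 ± 0.13 and the antisense transcript Hoxaas3 at 0.77 ± 0.22. In these last 4 lists 0 passed adjusted over the list alone, and in all lists of this paragraph 0 over all genes tested. Median, mean and test differed in sign in 9 lists, none of them past camera: loop of Henle and distal tubule, stroma, smooth muscle, leukocytes, skeletal muscle, hypoxia, imprinted genes, Hox genes and solute carriers. Of the 13 lists not past camera, loop of Henle and proximal tubule included, the median changed sign without 1 array in 8 and moved by over 1.5 times in 12, and 0 passed camera without 1 array.

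The 3 arrays allow 4 patterns of sign, mirror patterns counted once, so no share under 0.05 can be reached, and the smallest two-sided p is 0.25. The observed pattern was the 1 of 4 with the highest count each time. It gave 1757 rows at an unadjusted limma p under 0.05 against at most 1252 in the others, 130 rows at least 2-fold on every array against at most 42, and 16 lists against at most 1.

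Extreme values were one-sided on arrays 2 and 3, at a limit of 2 picked after other limits had been looked at. On array 2, 564 features lay below -2 and 99 above 2, while on array 3, 733 lay above 2 and 161 below -2, and 142 features were in both large tails, against 20.3 expected by chance. A difference between the ages and an excess of green signal may each be a source, and neither is excluded while the orientation of array 3 is not settled. As the source of the shared tail, a difference between the ages needs array 3 turned. In that orientation 0 lists passed camera, against 16 as deposited. Of the 180 features beyond 2 on both arrays, 80% went in opposite age directions with array 3 as deposited and 20% with it turned, and the shared tail is green on both only as deposited. Array 1 has the dye order of array 2, so either source would put the 142 features below 0 there; their median was 0.081 (quartiles -0.23 and 0.39), but that is 1 array.

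The lists lower at 11.5 dpc may reflect a trend along the oligonucleotide library, because medians of arrays 1 and 2 were -0.33 and -0.20 at library numbers 5001 to 6000, against -0.050 on array 3. Subtracting a running median argues against this as the whole source for 5 lists. Camera adjusted p was 4.0e-08 for the renal vesicle list, 0.000186 for matrix, 0.000702 for Notch, 0.000794 for ureteric bud and 0.00351 for endothelium. In that order, 93.2, 68.1, 60.2, 87.6 and 90.8% of the median shift was kept. Their mean log2 ratios went from -0.63 to -0.57, -0.45 to -0.32, -0.50 to -0.39, -0.35 to -0.29 and -0.25 to -0.17. Part of each shift may thus come from the trend, and a difference in age remains open and untested. The 8 called lists lost in that refit were 7 lower ones and oxidative phosphorylation, which was higher (camera adjusted p 0.0542 to 0.439). Of these, Wnt kept 47.6% of its median shift (camera adjusted p = 0.439). Both values meet the bounds set for the trend as a source in the 5 lists above. A trend may thus account for the Wnt call. The others kept 53.8 to 100.1%, so losing the call does not show the trend as their source, and it stays open for them. The cell cycle list had a median of -0.121 before and after (SD over members 0.36), and its call ended as its mean limma statistic less that of the other genes went from -0.56 to -0.37.

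Erythroid genes higher at 11.5 dpc could reflect a dye effect, which stays open. On the array of opposite dye order, 21 of the 27 measured members had the sign of their mean on the other arrays, and 6 with array 3 turned, so the answer rests on an orientation that is not settled. A dye term left the list at 0.36 (adjusted p = 0.000187) with array 3 as deposited, which argues against a dye effect as the whole source only under that orientation, since turning array 3 swaps the 2 terms. A larger share of the same blood cells at 11.5 dpc would move the members alike, and their means had an SD of 1.20 against a median standard error of 0.183, with Hbb-bh1 above Hba-a1 by 3.73 ± 1.10 (SD over 3 arrays). It stays open, because saturated spots or expression in other cells would also spread the members, and no member was lower adjusted over the list alone. A change in the kind of blood cell between the ages remains an untested hypothesis.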
